A study of Homo sapiens with 4 samples.

How the data were processed

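Poly(A)-selected RNA of ABZB cells was sequenced in 4 strand-specific, paired-end libraries of 2 x 150 bp, per the labels' protocols. The submitters' processing notes name FastQC, a read quality tool, and the human genome build hg19; the aligner, the counting program, the annotation release and any filter on reads are not given in the sources used here. The authors deposited 1 table of raw counts per Ensembl gene, whole numbers that were not normalized, for 63568 gene identifiers. How reads that match several genes were counted is not stated, so genes with near-identical copies are uncertain. All 37 mitochondrially encoded genes matched in the table are listed at 0 in every library, so these genes were not analysed here.

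Each count column was matched to its sample by its library name in the labels, and each sample to its group by its title. The groups are SCR (scramble vector) and KO (knockout vector), with 2 libraries each. The series describes the replicates as independent biological replicates but does not say whether libraries with the same number shared a day or culture. p-values rest on the spread between 2 libraries per arm, moderated across genes by the test, and take no account of the replicate number.

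Gene symbols came from a table of gene names and, where it had none, from GENCODE 29, matched on Ensembl identifiers without their version; 52526 of the 63568 identifiers had a symbol. Identifiers without one held between 1.35% and 1.69% of the counts of a library. No coordinates are given, because the annotation at hand is of another build than the one the submitters name. The clone name RP11-350G8.5 matched none of the name tables used here, so the planned tests of the targeted RNA and of its neighbouring genes were not run.

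Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), library sizes were scaled by TMM, and knockout was compared with scramble by the robust quasi-likelihood F test with group as the only term. p-values were adjusted by the Benjamini-Hochberg method over 17096 genes, with a threshold of 0.05. Fold changes are log2 of knockout over scramble, given with their standard errors (SE), taken as the change divided by the square root of the F statistic. Expression levels are CPM, counts scaled to a common library size, computed here with the TMM-scaled library sizes. Depth was 33862941 to 47485622 counts per library, so counting error matters mainly for genes with few counts.

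Before the data were examined, 37 gene lists with 1081 entries were fixed, covering stress responses, protein degradation, antigen presentation, cell cycle, metabolism, plasma cell identity and markers of other cell types; 1061 entries matched the table. The 33 lists with at least 5 tested genes were tested with camera (limma 3.58.1) on voom values, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Beside it stand camera with an estimated correlation and fry, which asks whether a list's genes move one way without comparing them with other genes. Members were also counted with p adjusted over the list alone. The named genes were fixed by a rule written beforehand: the 12 largest rises and 12 largest falls with a mean log2 CPM of at least 1, a symbol that is not a bare clone name and no overlap between the arms, the 4 members with the smallest p in the direction of each called list, and up to 2 members with p below the threshold in every other list. The rule asked for adjusted p, and for unadjusted p where fewer than 5 genes passed; 3 passed, so unadjusted p was used. Some genes that the rule selects are not reported here. Other genes are named as chosen after their values were seen.

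The gene test was checked on simulated counts drawn for the same 17096 genes with the genes' mean levels, the libraries' sizes and the estimated dispersions, 200 of them changed. At an adjusted p under 0.05, 9 of 67 genes changed 2-fold, 42 of 67 changed 4-fold and 60 of 66 changed 16-fold were recovered in the right direction, and 18 of 16896 unchanged genes were called. At an unadjusted p under 0.05, 48 of 67 genes changed 2-fold were recovered and 814 unchanged genes passed. The simulated libraries varied independently, while real libraries with the same number had deviations correlated at 0.54 across genes. The recovered shares therefore need not hold for the real libraries. A simulated list of 30 independent genes lowered 1.5-fold had a camera adjusted p of 5.17e-08 with the preset correlation and 0.738 with an estimated correlation, and none of 35 unmoved lists was called. The estimated-correlation test therefore missed this simulated shift. Because the simulated genes varied independently, the 35 unmoved lists cannot show how often the preset correlation calls lists whose genes vary together.

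Alternatives planned beforehand were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, other filters, a non-robust fit, a minimum fold change of 1.5, removal of immunoglobulin and mitochondrial genes, the replicate number as a block, and leaving out each library. Thinning to equal depth, removal of trends on GC content and transcript length, and an adjusted p below 0.1 were added after seeing the data.

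Lists with fewer than 5 tested genes were not tested by camera: the myeloid, erythroid, stroma and epithelium lists and the mitochondrially encoded genes.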

Results

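RNA sequencing was used to ask which transcripts change in bortezomib-resistant multiple myeloma cells when the long noncoding RNA RP11-350G8.5 is targeted with CRISPR-Cas9. ABZB is a bortezomib-resistant subclone of the plasmacytoma line AMO-1, bortezomib being a proteasome inhibitor, and its samples are labelled as treated with 10 nM of the drug. RNA was taken 7 days after transduction with a scramble vector (SCR) or a knockout vector (KO), with 2 libraries per arm. The libraries held 33862941 (SCR replicate 1), 40578356 (SCR replicate 2), 44083393 (KO replicate 1) and 47485622 counts (KO replicate 2), so both knockout libraries were deeper than both scramble libraries. Across 17096 tested genes, log2 CPM correlated at 0.972 between the scramble libraries and at 0.981 between the knockout libraries, and at 0.979 between SCR replicate 1 and KO replicate 1. These correlations are across genes, which are not independent replicates. Libraries of the same arm differed far beyond sampling noise and were counted as separate samples.

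The targeted RNA was not analysed here, because its clone name is paired with no gene identifier in the name tables used, and the arms therefore rest on the labels alone. Markers of other cell types were counted in every library. Among them 1 of myeloid cells, 1 of the erythroid and platelet lineage and 3 of stroma and epithelium were expressed well enough to be tested. Their highest genes were ITGAM at 0.738 to 1.15 CPM, ITGA2B at 0.119 to 1.39 CPM and CDH1 at 3.25 to 11 CPM. The highest gene of the T and NK cell list was TRBC2 at 32.3 to 48.9 CPM, and that of the B cell list was CIITA at 193 to 448 CPM. Neither the B cell list (12 genes tested, median 0.08) nor the T and NK cell list (5 genes, median 0.14) was called, each with an adjusted p of 0.683 by camera from limma. Both medians turned sign with the library left out, from -0.71 (without KO replicate 1) to 0.45 (without SCR replicate 1) for the B cell list and from -0.12 (without SCR replicate 2) to 0.50 (without SCR replicate 1) for the T and NK cell list.

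In the comparison of knockout with scramble, 3 transcripts fell almost to nothing in the knockout libraries. They were the pseudogenes CLUHP4 (ENSG00000249003.1) and CLUHP5 (ENSG00000230468.1), copies of the mitochondrial mRNA-binding gene CLUH, and ENSG00000221795.1, an identifier with no symbol. CLUHP4 stood at 32.4 and 32.7 CPM in the scramble libraries and at 0.276 and 0.538 CPM in the knockout libraries, a log2 change of -6.30 ± 0.39 (SE). CLUHP5 changed by -6.50 ± 0.34 and ENSG00000221795 by -6.55 ± 0.39, each with an adjusted p of 0.00575 by edgeR's quasi-likelihood test. Because these pseudogenes resemble one another and CLUH, their counts are uncertain. CLUH itself was at 178 and 165 CPM in the scramble and at 283 and 375 CPM in the knockout libraries (log2 change 0.94 ± 0.20, adjusted p = 0.164 by edgeR).

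No gene rose past an adjusted p of 0.05 and these 3 fell, by edgeR. At an unadjusted p under 0.05, 1325 genes were higher and 1124 lower in the knockout libraries, against 855 expected by chance among 17096. DESeq2 called 356 genes higher and 264 lower, and limma-voom called 0 higher and 3 lower. Without the filter on low counts, edgeR called 590 higher and 350 lower. With the replicate number as a block, it called 1211 higher and 896 lower. Libraries with the same number had deviations correlated at 0.54 across genes, but the labels do not say that they shared a day or culture. The small count of calls thus depends on the test, on the filter on low counts and on leaving the replicate number out. The edgeR counts moved when a library was left out: 10 higher and 27 lower without SCR replicate 1, 2 and 13 without SCR replicate 2, 333 and 260 without KO replicate 1, and 47 and 54 without KO replicate 2. The 3 transcripts were among the calls each time. The groups of SCR and KO values did not overlap in 46.9% of the genes, against 33.3% expected by chance for 2 libraries against 2.

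The other genes with the largest differences did not pass the adjusted threshold by edgeR, and their values are given without a verdict. ESRP1, an epithelial splicing regulator, was at 9.31 and 39.2 CPM in the scramble libraries and at 0.230 and 0.194 CPM in the knockout libraries, a log2 change of -6.82 ± 0.82 (adjusted p = 0.0994 by edgeR and 3.1e-26 by DESeq2). The log2 change was -5.41 ± 0.81 for TMTC1, -5.11 ± 0.64 for RCAN2, an inhibitor of calcineurin, -4.54 ± 0.66 for DMGDH, a mitochondrial enzyme of choline breakdown, and -3.90 ± 0.60 for BEST1, a chloride channel. LINC01229 (-3.16 ± 0.35), the semaphorin SEMA3B (-2.89 ± 0.70), the cold-sensing channel TRPM8 (-2.86 ± 0.61), the LIM homeobox factor LHX3 (-2.71 ± 0.26) and the synaptic vesicle gene SV2B (-2.62 ± 0.37) completed the lower set. On the higher side, the log2 change was 2.51 ± 0.45 for NRGN, 2.42 ± 0.42 for the carbonic anhydrase CA2, 2.39 ± 0.39 for the immunoglobulin segment IGLV3-1, 2.28 ± 0.39 for RNVU1-14, 2.22 ± 0.73 for ID1 and 2.20 ± 0.27 for SMOC1. COCH (2.16 ± 0.52), RASSF2 (2.10 ± 0.41), ARHGDIB (2.09 ± 0.34), CRMP1 (2.05 ± 0.69) and the interferon-induced IFIT3 (2.02 ± 0.40) followed. IGLV3-1 and RNVU1-14, a variant U1 small nuclear RNA, belong to families of close copies and are uncertain. Some of these values rested on 1 library: ID1 was at 0.92 without KO replicate 2, CRMP1 at 3.56 without SCR replicate 1 and 1.32 without SCR replicate 2, and TRPM8 at -1.90 without SCR replicate 2.

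**Figure D1:**
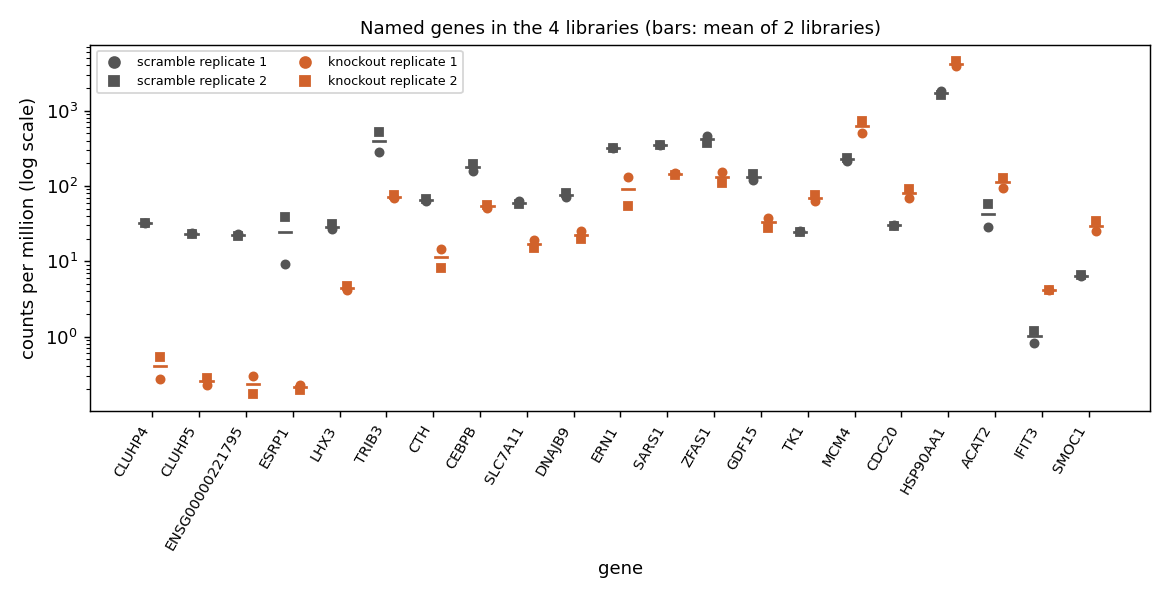
CPM (log axis) of named genes in the 4 libraries; circles are replicate 1, squares replicate 2, grey scramble, orange knockout, and bars the mean of 2 libraries. CLUHP4, CLUHP5, ENSG00000221795 and ESRP1 lie below 1 CPM in both knockout libraries.

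Of the 33 gene lists tested, 13 were higher and 5 lower in the knockout libraries by camera with the preset correlation. None was called with a correlation estimated from the 4 libraries (adjusted p of 0.314 or more for every list) or by fry (0.0873 or more). No list member passed the adjusted threshold over all genes by edgeR, so the counts of members below are adjusted over the list alone.

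Genes driven by ATF4, the transcription factor of the integrated stress response, were lower in the knockout libraries. All 29 tested members had negative log2 changes, with a median of -1.16, and 25 fell when adjusted over the list alone (26 at an unadjusted p under 0.05, 13 by DESeq2 over all genes). TRIB3, a pseudokinase induced by endoplasmic reticulum stress, was at 283 and 514 CPM in scramble and 68.3 and 74.8 CPM in knockout, a log2 change of -2.48 ± 0.30. The cystathionine lyase CTH fell by 2.51 ± 0.31 on the log2 scale, the cystine transporter SLC7A11 by 1.81 ± 0.23, and the stress-induced factor CEBPB by 1.72 ± 0.20. By camera the adjusted p was 8.9e-24, and adjusted p = 0.314 with an estimated correlation. The cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA and of which many are ATF4 targets, had 14 of 20 members below 0 (median -0.37). Of these, 8 fell and 1 (FARSA) rose when adjusted over the list alone. SARS1 fell by 1.27 ± 0.17, WARS1 by 1.30 ± 0.21, GARS1 by 1.00 ± 0.18 and AARS1 by 0.77 ± 0.18 on the log2 scale. This list had a camera adjusted p of 0.000241, and adjusted p = 0.314 with an estimated correlation.

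The unfolded protein response answers misfolded protein in the endoplasmic reticulum. In the list for IRE1-XBP1, secretion and degradation of misfolded protein, 32 of 33 members were below 0 (median -0.46) and 6 fell when adjusted over the list alone. The chaperone cofactor DNAJB9 fell by 1.75 ± 0.22 and the sensor kinase ERN1 (IRE1) by 1.79 ± 0.38 on the log2 scale. The coat protein SEC24D fell by 1.11 ± 0.23 and the translocon-associated SSR3 by 1.08 ± 0.20. The camera test of the list gave an adjusted p of 8.5e-10, and adjusted p = 0.314 with an estimated correlation. The ATF6 chaperone list was not called (median 0.10, adjusted p = 0.852 by camera), with 12 members above and 9 below 0. The median of this list ranged from 0.02 to 0.15 when a library was left out. In it DERL3, a component of the retrotranslocation machinery, rose (1.18 ± 0.20) and SEL1L, its degradation partner, fell (-1.02 ± 0.19) when adjusted over the list alone.

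Genes of DNA replication were higher in the knockout libraries. All 41 members had positive log2 changes (median 0.98), and 38 rose when adjusted over the list alone (38 at an unadjusted p under 0.05, 25 by DESeq2 over all genes). Thymidine kinase TK1 was at 25.1 and 24.2 CPM in scramble and 63.9 and 76.3 CPM in knockout, a log2 change of 1.51 ± 0.21. The replicative helicase subunits MCM4 and MCM7 rose by 1.47 ± 0.23 and 1.30 ± 0.20, and the helicase cofactor GINS2 by 1.62 ± 0.27. Camera gave the list an adjusted p of 2.0e-28, and adjusted p = 0.431 with an estimated correlation. Of the genes of G2 and mitosis, all 40 were above 0 (median 0.67) and 24 rose when adjusted over the list alone. The anaphase activator CDC20 rose by 1.43 ± 0.23, the checkpoint gene MAD2L1 by 1.05 ± 0.19, the ubiquitin-conjugating enzyme UBE2C by 1.07 ± 0.20 and the phosphatase CDC25B by 0.96 ± 0.20. By camera the adjusted p was 9.6e-20, and adjusted p = 0.314 with an estimated correlation. Replication-dependent histones were not called (13 genes, median 0.62, adjusted p = 0.265 by camera, and 0.000331 without KO replicate 2). Their median turned to -0.05 without KO replicate 1 and was 0.35 without SCR replicate 2. Most transcripts of this class lack a poly(A) tail, and its named members were H2BC12 (0.76 ± 0.19) and H2AC6 (-0.74 ± 0.28, or -0.49 without KO replicate 2).

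The heat shock and proteasome lists were called higher by camera with the preset correlation, though not with an estimated correlation. Of 22 heat shock genes, 19 were above 0 (median 0.51) and 7 rose when adjusted over the list alone. The chaperone HSP90AA1 was at 1809 and 1611 CPM in scramble and at 3938 and 4536 CPM in knockout, a log2 change of 1.31 ± 0.18. HSPA8 rose by 1.14 ± 0.25, the co-chaperone FKBP4 by 0.77 ± 0.18 and HSPA4L by 1.70 ± 0.41. HSPA1A (0.01 ± 1.57), HSPA1B (0.01 ± 1.54), DNAJB1 (0.27 ± 0.70) and BAG3 (0.28 ± 0.28), named after their values were seen, differed by no more than their standard errors. HSPA1B was at 659 and 29.5 CPM in scramble and at 606 and 86.8 CPM in knockout. The camera test of the list gave an adjusted p of 2.4e-06, and adjusted p = 0.314 with an estimated correlation. Of 32 proteasome subunits, 31 were above 0 (median 0.39) and none passed when adjusted over the list alone by edgeR, although 8 had an unadjusted p under 0.05 and DESeq2 called 0. The log2 changes with the smallest p were 0.59 ± 0.17 for PSMD1, 0.68 ± 0.21 for PSMD2, 0.59 ± 0.19 for PSMA3 and 0.57 ± 0.19 for PSMC3. Camera gave the list an adjusted p of 1.8e-07, and adjusted p = 0.431 with an estimated correlation. In contrast NFE2L1, the factor that drives proteasome gene transcription, was at 875 and 1007 CPM in scramble and 418 and 404 CPM in knockout (log2 change -1.20 ± 0.18), and it fell when adjusted over the list of genes tied to proteasome inhibitor resistance alone. SQSTM1, a selective autophagy receptor, and ERN1 are also on that list and fell as well, SQSTM1 by 1.01 ± 0.18 on the log2 scale. That list as a whole was not called (16 genes, adjusted p = 0.784 by camera), and its median (0.14) and mean (-0.15) had opposite signs. Its median ranged from 0.04 to 0.08 when a library was left out.

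Of 74 nuclear genes of oxidative phosphorylation, 69 were above 0 (median 0.40), none passed when adjusted over the list alone by edgeR, 23 had an unadjusted p under 0.05, and DESeq2 called 2. The log2 change was 0.93 ± 0.19 for NDUFS5, 0.89 ± 0.19 for ATP5MC3, 0.80 ± 0.20 for NDUFA3 and 0.73 ± 0.19 for ATP5PD. By camera the adjusted p was 2.0e-14, and adjusted p = 0.455 with an estimated correlation. Of 24 genes of cholesterol synthesis, 23 were above 0 (median 0.65) and 8 rose when adjusted over the list alone. Among these, ACAT2 rose by 1.39 ± 0.35, EBP by 1.03 ± 0.23 and HSD17B7 by 0.97 ± 0.22. The camera test of the list gave an adjusted p of 8.5e-09, and adjusted p = 0.571 with an estimated correlation; its median was 0.31 without SCR replicate 1 and 1.20 without SCR replicate 2. The glycolysis and hypoxia list had a camera adjusted p of 0.0206, and adjusted p = 0.846 with an estimated correlation. Its median was 0.16, and it turned to -0.14 without SCR replicate 2 (0.167) and to -0.11 without KO replicate 1 (0.348), the adjusted p in parentheses. It was 0.94 without SCR replicate 1 and 0.55 without KO replicate 2, and the list was not called once trends on GC content and length were removed (0.0579). Among its members above 0, those with the smallest p were PGAM1 (0.76 ± 0.19), TPI1 (0.77 ± 0.26), ALDOA (0.82 ± 0.28) and ALDOC (1.23 ± 0.44). VEGFA, named after its values were seen, had a smaller p than these and a log2 change of -1.09 ± 0.25. Without SCR replicate 1 the log2 change was 1.17 for TPI1, 1.25 for ALDOA and 2.04 for ALDOC, and without SCR replicate 2 it was 0.48, 0.51 and 0.72. Fatty acid synthesis was not called (12 genes, median 0.15, adjusted p = 0.131 by camera, and 0.00495 without SCR replicate 2), with FASN at 0.61 ± 0.21 and ACLY at 0.51 ± 0.20. Its median was 0.10 without SCR replicate 1, 0.43 without SCR replicate 2, 0.28 without KO replicate 1 and 0.06 without KO replicate 2.

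Of 31 interferon-stimulated genes, 26 were above 0 (median 0.43), and IFIT3 and the GTPase GBP1 (2.40 ± 0.54, from 0.266 and 0.238 CPM to 1.06 and 1.62 CPM) rose when adjusted over the list alone. BST2 (tetherin) had a log2 change of 0.94 ± 0.28 (0.53 without KO replicate 2) and PARP14 one of 1.29 ± 0.39. Camera gave the list an adjusted p of 0.000618, and adjusted p = 0.314 with an estimated correlation; its median was 0.68 without SCR replicate 1 and 0.75 without SCR replicate 2. The MHC class I list had a camera adjusted p of 0.0206, and adjusted p = 0.431 with an estimated correlation. Its median was 0.22, and it was not called without SCR replicate 2 (0.08, median 0.11), KO replicate 1 (0.0619) or KO replicate 2 (0.119), nor once trends on GC content and length were removed (0.125). Its members with the smallest p were the transactivator NLRC5 (0.64 ± 0.21), PSMB8 (0.50 ± 0.18), TAP1 (0.59 ± 0.22) and TAPBP (0.53 ± 0.22). TAP1 was at 0.35 without KO replicate 2, and TAPBP at 0.34 without SCR replicate 1 and 0.80 without SCR replicate 2. The MHC class II list had a camera adjusted p of 0.0206, and adjusted p = 0.801 with an estimated correlation. Its median was 0.31, or 0.05 without SCR replicate 1 and 0.47 without SCR replicate 2, and it was not called without SCR replicate 1 (0.735) or KO replicate 2 (0.154). Its members with the smallest p were HLA-DPB1 (0.52 ± 0.18), HLA-DRA (0.44 ± 0.20), HLA-DOA (0.39 ± 0.19) and HLA-DMA (0.39 ± 0.21). HLA-DRA was at 0.27 and HLA-DMA at 0.22 without SCR replicate 1, and they were at 0.68 and 0.63 without SCR replicate 2. The list of danger signals of immunogenic cell death was not called (19 genes, median 0.13, adjusted p = 0.132 by camera, and 0.0244 without KO replicate 2). Its median was 0.21 without KO replicate 1 and 0.08 without KO replicate 2. Within it HSP90AA1 rose when adjusted over the list alone, and the nuclear protein gene HMGB1 had a log2 change of 0.75 ± 0.19. The NK cell ligands were not called (10 genes, median 0.04, adjusted p = 0.265 by camera). Their median ranged from 0.08 to 0.21 when a library was left out. MICB had a log2 change of 0.79 ± 0.24, and ULBP3 was near the floor with 2 and 3 counts in the scramble libraries.

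Noncoding and RNA-processing genes gave mixed results. Of 29 well-known long noncoding RNAs, 25 were below 0 (median -0.51, and -0.27 without KO replicate 2). ZFAS1 was at 468 and 368 CPM in scramble and 154 and 111 CPM in knockout, a log2 change of -1.66 ± 0.24, and ZFAS1, SNHG5 (-1.39 ± 0.27) and SNHG8 (-1.15 ± 0.25), all hosts of small nucleolar RNAs, fell when adjusted over the list alone. EPB41L4A-AS1 had a log2 change of -1.22 ± 0.37, or -0.71 without SCR replicate 1. DANCR, named after its values were seen, rose (1.08 ± 0.24). By camera the adjusted p was 4.4e-05, and adjusted p = 0.455 with an estimated correlation. Ribosomal protein genes had a median of -0.13 over 75 members, with 58 below 0 and none past an unadjusted p of 0.05 by edgeR or called by DESeq2. Those with the smallest p were RPS23 (-0.42 ± 0.20), RPL10 (-0.37 ± 0.20), RPS4X (-0.32 ± 0.18) and RPS6 (-0.36 ± 0.21). RPL10, RPS4X and RPS6 were at -0.21, -0.20 and -0.16 without SCR replicate 1 and at -0.20 each without KO replicate 2, and RPS23 was at -0.20 without SCR replicate 2. Their list had a camera adjusted p of 0.0206, and adjusted p = 0.846 with an estimated correlation. Its direction turned without SCR replicate 1 (median 0.06, adjusted p 0.301), and it was not called without KO replicate 2 (median -0.02, 0.475). The median was -0.30 without SCR replicate 2 and -0.20 without KO replicate 1. Ribosome biogenesis genes had a median of 0.27 over 39 members, with SRM at 0.61 ± 0.21, NHP2 at 0.75 ± 0.26, TSR1 at 0.45 ± 0.18 and MRTO4 at 0.63 ± 0.26. Without KO replicate 2, SRM was at 0.39 and MRTO4 at 0.27, and without KO replicate 1 MRTO4 was at 0.96. The camera adjusted p was 0.000418, and adjusted p = 0.571 with an estimated correlation; without KO replicate 2 the list was not called (0.224, median 0.13). RNA decay and splicing genes had a median of 0.10 over 31 members; HNRNPA2B1 rose when adjusted over the list alone (0.87 ± 0.16), with SRSF2 at 0.91 ± 0.23, TRA2A at 0.59 ± 0.19 and SRSF7 at 0.82 ± 0.26 (0.54 without SCR replicate 2). The camera adjusted p was 0.0206, and adjusted p = 0.431 with an estimated correlation, and the call was lost without SCR replicate 2 (0.0652) or KO replicate 1 (0.07). The median was 0.17 without SCR replicate 1. The adhesion list (23 genes, median 0.33) had a camera adjusted p of 0.0115, and adjusted p = 0.534 with an estimated correlation. Its median was 0.51 without SCR replicate 1 and 0.10 without SCR replicate 2, where it was not called (0.12). Its named members were S100A10 (1.74 ± 0.44), S1PR1 (0.91 ± 0.24), CD81 (0.75 ± 0.21) and CXCR4 (0.60 ± 0.18). SELPLG, named after its values were seen, had a smaller p than CXCR4 and a log2 change of -0.72 ± 0.21.

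**Figure D2:**
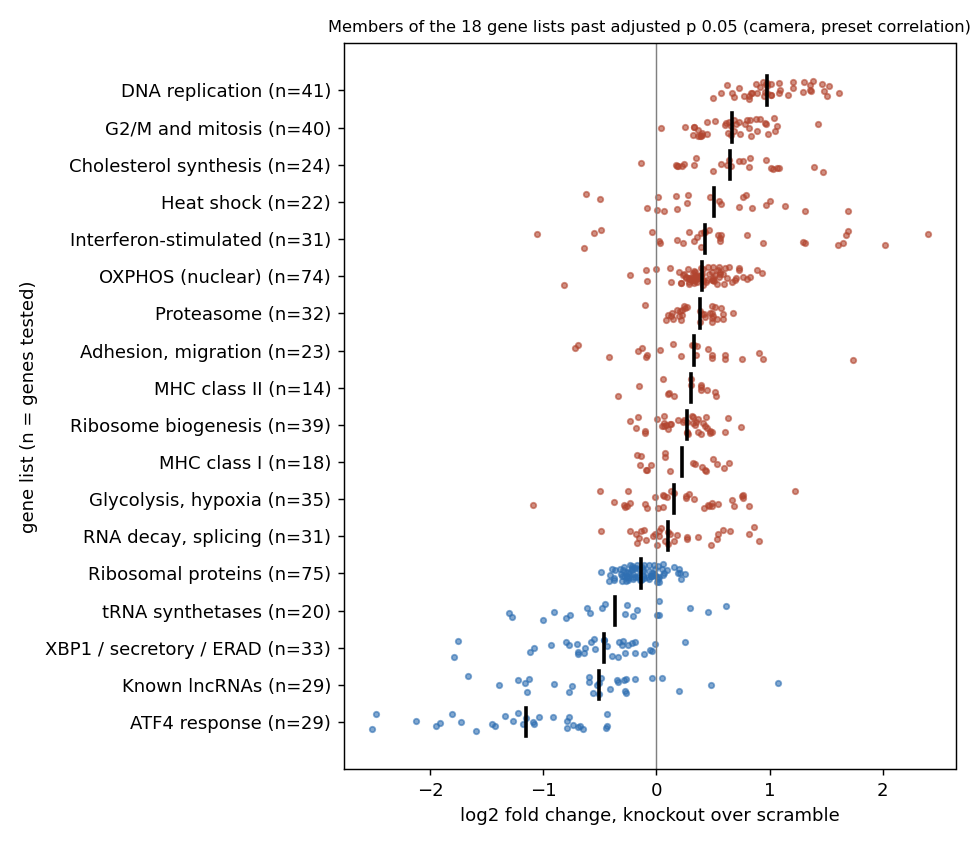
Log2 fold change of knockout over scramble (horizontal axis) for each tested member of the 18 gene lists past an adjusted p of 0.05 by camera with the preset correlation; points are genes, black bars medians, red lists called higher and blue lists called lower. The ATF4 list lies wholly below 0 and the DNA replication list wholly above 0.

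The remaining lists were not called by camera, and some of their members differed. Among genes of plasma cell identity (32 genes, adjusted p = 0.683 by camera), DERL3 rose and the costimulatory receptor CD28 fell by 0.98 ± 0.17 on the log2 scale when adjusted over the list alone. CCND3 (1.21 ± 0.27) and SLAMF7 (-0.67 ± 0.17), named after their values were seen, also passed over that list, whose median (-0.06) and mean (0.06) had opposite signs. Among p53 targets (34 genes, median 0.03, mean -0.07, adjusted p = 0.852 by camera, which gave the sign of the mean), the stress cytokine GDF15 fell by 2.00 ± 0.24 on the log2 scale when adjusted over the list alone. TNFRSF10B, the death receptor DR5, had a log2 change of -0.77 ± 0.20. Among autophagy and lysosome genes (35 genes, median -0.02, adjusted p = 0.258 by camera, and 0.0297 without SCR replicate 1), MAP1LC3B fell by 1.40 ± 0.25 and SQSTM1 by 1.01 ± 0.18 on the log2 scale when adjusted over the list alone. Among NRF2 targets (22 genes, median 0.09, adjusted p = 0.491 by camera), SLC7A11 fell, and the peroxidase PRDX1 (1.19 ± 0.18) and AKR1B1 (0.86 ± 0.22), the latter named after its values were seen, rose when adjusted over the list alone. The median of the NRF2 targets ranged from 0.04 to 0.18 when a library was left out. In the BCL-2 and caspase list (27 genes, median -0.17, adjusted p = 0.782 by camera), no member passed when adjusted over the list alone by edgeR, 4 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 1. The inhibitor of apoptosis XIAP had a log2 change of -0.70 ± 0.19 and the pro-apoptotic BIK a log2 change of 1.09 ± 0.32. The median of this list turned to 0.05 without SCR replicate 1 and to 0.03 without KO replicate 2. NF-kappaB targets (21 genes, median -0.09, adjusted p = 0.515 by camera, and 0.0231 without SCR replicate 2) held NFKBIA at -0.82 ± 0.27 and TNFAIP2 at -3.06 ± 1.07. TNFAIP2 was near the floor, at 1.51 and 0.238 CPM in scramble and 0.161 and 0.0431 CPM in knockout. Without SCR replicate 1, NFKBIA was at -0.46 and TNFAIP2 at -1.19, and the median of the list turned to 0.11. That median was -0.33 without SCR replicate 2 and -0.21 without KO replicate 1. Immediate early genes (30 genes, median -0.06, mean 0.17, adjusted p = 0.683 by camera, which gave the sign of the mean) held KLF2 at 1.01 ± 0.28 and DUSP6 at 0.83 ± 0.35 (0.50 without KO replicate 1). Their median was 0.62 without SCR replicate 1 (adjusted p 0.00498 by camera), -0.32 without SCR replicate 2 (0.0259), -0.35 without KO replicate 1 (0.00375) and 0.32 without KO replicate 2 (3.0e-10), so the direction turned with the library left out. In the B cell list SPIB had a log2 change of 1.16 ± 0.45, or 0.43 without KO replicate 2. The medians of the plasma cell, autophagy and p53 lists, all near 0, also turned sign when 1 library was left out, ranging from -0.10 to 0.15, from -0.11 to 0.04 and from -0.07 to 0.24.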

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

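The adjusted p below 0.1, the thinning to equal depth and the removal of GC and length trends were chosen after seeing the data. The 3 genes called lower by edgeR were shared with the calls of every alternative. RLE and upper-quartile scaling, a mean CPM of at least 1, limma-voom, a fit that was not robust, removal of immunoglobulin and mitochondrial genes, a minimum fold change of 1.5, thinning and the GC and length correction each gave 0 higher and 3 lower. The count moved to 590 higher and 350 lower without the filter on low counts, to 356 and 264 with DESeq2, and to 6 and 27 at an adjusted p below 0.1; the cause was not tested for the first 2, and a looser threshold makes the last. Leaving out a library gave from 2 to 333 higher and from 13 to 260 lower; an arm then has 1 library, assumed to vary like the other arm. With the replicate number as a block, edgeR called 1211 higher and 896 lower; libraries with the same number had deviations correlated at 0.54 across genes, and nothing in the labels says that they shared a day or culture. Of the 13 lists called higher and 5 called lower, 0 and 0 were called with an estimated correlation and 0 and 0 by fry. Keeping a call when a library is left out is weak support, because the lists were called in these same libraries. The immediate early list, not called on all 4 libraries, had medians from -0.35 to 0.62 over the libraries left out. Removal of GC and length trends ended the calls of the glycolysis and hypoxia list (adjusted p 0.0579 by camera) and the MHC class I list (0.125); the cause was not tested. The glycolysis and hypoxia list reversed without SCR replicate 2 (adjusted p 0.167 by camera) and without KO replicate 1 (0.348), its adjusted p ranging from 3.3e-19 to 0.348 over the libraries left out. The ribosomal protein list reversed without SCR replicate 1 (0.301), with a range from 1.4e-07 to 0.475; the cause was not tested. Of 119 named genes, 0 changed sign in 1900 alternative values, and DESeq2 called 74 of the 117 it gave an adjusted p. The genes were selected in these same libraries for large changes or small p, so neither count is an independent check. Tests of the targeted RNA and its neighbours under other settings were not run. Depth limits genes near 0 CPM in an arm, such as ULBP3.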

Other observations

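Tubulin genes, which encode the subunits of microtubules and were chosen after their values were seen, had positive log2 changes in 15 of 20 cases (median 0.85). The lowest adjusted p over all genes was 0.124 by edgeR, for TUBA4A, and the family was picked for its values, so a p adjusted over it alone is not given. TUBB4A had a log2 change of 0.99 ± 0.21 (SE), TUBA1B of 1.66 ± 0.42 and TUBA4A of 1.37 ± 0.23, while TUBE1, the epsilon tubulin, had one of -1.48 ± 0.26. Tubulin genes have close copies, so single members are uncertain. Other genes chosen after their values were seen did not pass over all genes by edgeR: CCPG1, a receptor for autophagy of the endoplasmic reticulum, had a log2 change of -2.38 ± 0.27, the glycine transporter SLC6A9 of -2.01 ± 0.22, the DNA methyltransferase DNMT3B of 1.47 ± 0.19 and the recombination gene RAD54L of 1.86 ± 0.24. The plasma cell factors IRF4 (-0.08 ± 0.19) and XBP1 (-0.22 ± 0.20) differed by about their standard errors or less.

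All tests in the paragraphs that follow were chosen after the result was seen, except the test of decay factors and the leaving out of each library. Unequal depth cannot account for the near-complete loss of CLUHP4, CLUHP5 and ENSG00000221795, because the knockout libraries were the deeper ones. CLUHP5 kept a log2 change of -6.57 after thinning to equal totals. Thinning could hardly have changed that value, so it adds no support. Reads given to the parent gene CLUH or its copy CLUHP3 instead cannot be told apart from a loss of the pseudogene transcripts. These gained 2.89 times the CPM that CLUHP4 and CLUHP5 lost (160 against 55.2 CPM, with a spread of 42.7 CPM), more than reassigned reads alone would give, and how such reads were counted is not stated. An effect of the knockout vector itself stays open and untested.

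For the lower ATF4-response genes, the median log2 change was -1.22 after removal of GC and length trends, so these do not explain it. The median was -1.15 after thinning, a step that could hardly change values already scaled to library size. It was at most -0.88 when any 1 library was left out, so no single library explains the fall. More active nonsense-mediated decay, which degrades ATF4 mRNA among others, was expected beforehand to lower the genes of decay factors. The 10 decay-factor genes had a median of 0.002 with an interquartile range of 0.239, from SMG1 at -0.49 to UPF1 at 0.37. The expected fall was thus not seen, but decay of the ATF4-response transcripts was not measured, so this explanation stays open. A lower integrated stress response in knockout cells may also account for the pattern, and was not tested apart from these alternatives.

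Of the 12 noncoding hosts of small nucleolar RNAs on the list of long noncoding RNAs, a group formed after values were seen, 10 had negative log2 changes (median -0.59). At an unadjusted p under 0.05 by edgeR, 6 were lower and 1, DANCR, was higher. A general fall of transcripts with a 5' terminal oligopyrimidine tract, which ribosomal protein mRNAs share, stays open. The ribosomal protein median lay 0.463 above that of the hosts, and from 0.31 (without SCR replicate 2) to 0.682 (without SCR replicate 1) when 1 library was left out, but a group chosen for its values cannot exclude that explanation. Nonsense-mediated decay was not tested on these hosts.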
